A study of Episyrphus balteatus with 30 samples.

How the data were processed

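RNA was sequenced from 30 samples of the marmalade hoverfly in 10 groups of 3 replicates, covering eggs, larvae, pupae and 7 parts of adults. The deposited table holds RSEM expected counts per unigene and library (expected_counts per the file headers and values), and 7.17% of its values are not whole numbers. The authors name RSEM 1.3.1 and DESeq2 1.24.0 in their processing notes, and the deposited file names point to a Trinity assembly from which some unigenes were removed, without saying which. A second set of deposited columns, also expected_counts, equals the mean of the 3 libraries of each group to within 3.3e-05 and was used only for that check. The deposited assembly holds 1 nucleotide sequence (other unit: sequence, per the labels) for each of the 84945 unigenes, with a median length of 418 nt. The authors' table gives a best hit in the NR protein database for 43244 unigenes (50.9%) and a Swiss-Prot hit for 29336, and gene names in the text are these hits. No genome was at hand, and the supplied RefSeq gene table matched 0 of the unigene names.

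Total counts per library ranged from 9851305 to 20202205. A unigene with 0 counts in a group was given a floor of 3 counts over the summed libraries of the group, and a fold against it is printed as a lower bound ("at least"). Where several groups with 0 counts form 1 side of a comparison, the mean of their floors was used. With 1 to 3 counts in a group, the ratio of means is given with the exact 95% Poisson interval of that count. These floors range from 0.0614 CPM in the body to 0.137 CPM in the thorax. Floors and intervals cover counting error only, since PCR copies are not independent molecules.

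Counts were rounded to whole numbers. Unigenes were kept by filterByExpr at its defaults (a minimum count of 10), which left 32342 unigenes with 99.6% of the counts. One model with 10 group means was fitted over all 30 libraries with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, common dispersion 0.0469) in R 4.3.3 with limma 3.58.1. P values were adjusted by the Benjamini-Hochberg method over the 32342 unigenes. A unigene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 10 comparisons were larva against egg, pupa against larva, the mean of the 7 adult parts against pupa, and each adult part against the mean of the 6 others. A unigene was called specific to a group when each of the 9 contrasts of that group with another group passed the same thresholds. The standard error of a log2 fold change is its size divided by the square root of F. Nothing says that replicates came from separate cohorts, so p values measure the spread between these samples.

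Levels of a unigene are TMM-normalised CPM with the SD over 3 libraries. Means, figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Near-identical unigenes were searched with blastn 2.17.0 and seqtk 1.5-r133 (at least 95% identity over 150 nt).

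The comparisons, the 32 gene lists, the rule for named unigenes and the first set of alternatives were chosen before the data were examined. Lists were matched by words in the descriptions. They were odorant receptors, gustatory receptors, ionotropic receptors, odorant-binding proteins, chemosensory proteins, sensory neuron membrane proteins, phototransduction, muscle structure, oxidative phosphorylation, cuticle proteins, chitin metabolism, digestive enzymes, yolk and eggshell, testis and axoneme, embryonic patterning, cell cycle and DNA replication, ecdysone pathway, juvenile hormone pathway, immunity, storage proteins, neuropeptide signalling, synapse, circadian clock, ribosomal proteins, heat shock proteins, pigment and tanning, cytochrome P450, glutathione S-transferases, carboxylesterases, fat body, haemocyte, and aphid or endosymbiont annotation. Lists share members: the fat body list holds some of the storage proteins, and the haemocyte list holds phenoloxidases of the pigment list. Each list was tested in each comparison with camera from limma at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. The test was repeated with a correlation estimated from the residuals. Of 320 pairs of a list and a comparison, 132 had an adjusted p under 0.05 with the preset correlation, and 39 of these also with the estimated correlation.

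Unigenes were named by this rule. From each list assigned to a comparison, the 2 called members with the largest absolute log2 fold change and at least 5 CPM on the higher side were taken. The 6 largest increases and 4 largest decreases with an informative description, at least 50 CPM on the higher side and no overlap between the libraries of both sides were added, with 1 unigene per description. For each group, the 5 most abundant specific unigenes with an informative description were added. Where an aphid-annotated unigene was picked from a list, the pick was repeated without such unigenes, a step chosen after the data were seen. The rule named 221 unigenes, and the text gives those that show each group best. The Hox unigenes of the closing section were picked by gene name, 1 per Hox gene by the most counts.

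Alternatives to the main settings were RLE and upper quartile scaling, no count filter, a strict filter (at least 5 CPM in at least 3 libraries), DESeq2 1.42.0, a replicate block, counts summed over unigenes with the same annotation, only the libraries compared, each library left out in turn, and lists matched in Swiss-Prot descriptions alone. Leaving out aphid-annotated unigenes was added after the data were seen. The model was tested on simulated data with 23571 unigenes. In the comparison of larva with egg it called 94% of unigenes raised 3-fold and 74% of unigenes lowered to 0.33 of their level. It also called 5 of 23371 unchanged unigenes. Nearly all simulated unigenes were unchanged, whereas 17975 of 32342 tested unigenes were called in the real comparison. The simulated rates may therefore not hold for the real data.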

Results

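Transcript levels were measured by RNA sequencing in the marmalade hoverfly Episyrphus balteatus, whose larvae feed on aphids. The 30 libraries fell into 10 groups of 3 replicates. These were eggs taken 1 day after laying, larvae mixed over 4 stages, pupae taken 2 days after pupation, and 7 parts of unmated adults of both sexes taken 1 day after emergence (antenna, head without antennae and proboscis, proboscis, thorax without legs, leg, wing, and body, which is the abdomen). A sample pooled 100 eggs, antennae, proboscises, legs or wings, 30 heads, thoraces or abdomens, or 10 larvae or pupae. The libraries held 9851305 to 20202205 estimated read counts each over 84945 assembled transcripts (unigenes), of which 32342 had enough counts to be tested. Levels are TMM-normalised CPM (counts scaled to the size of the library), given as mean ± SD (n = 3 libraries), and a unigene is called higher or lower at an adjusted p under 0.05 with at least a 2-fold change. For each gene list, the first adjusted p is that of the camera test with a preset correlation between unigenes, and the second that with an estimated correlation. Gene names are those of the best database hit of a unigene ("annotated as"), and with no genome matched to the unigenes no chromosome position can be given.

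All 30 libraries correlated best with a library of their own group. The lowest Spearman correlation across unigenes within a group was 0.923 (egg replicates 1 and 3), and the highest between groups was 0.922 (proboscis replicate 3 and leg replicate 3). The first principal component held 31.2% of the variance and set larvae and pupae apart from the adult parts other than the body, and the second held 16.0% and had eggs and then antennae at its low end.

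**Figure D1:**
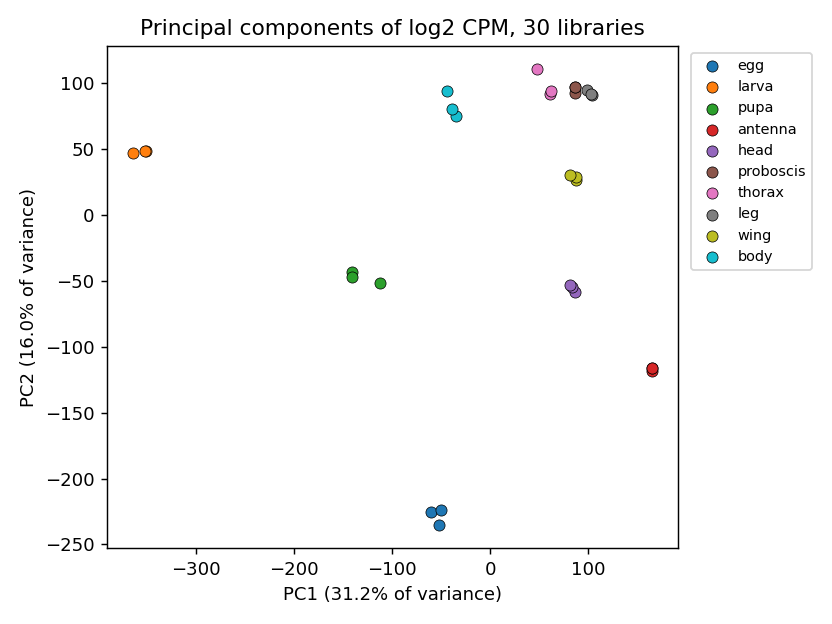
Each point is 1 of the 30 libraries, placed by the first (horizontal axis, 31.2% of the variance) and the second (vertical axis, 16.0%) principal component of log2 CPM and coloured by group. The 3 libraries of each group lie together, with proboscis, leg and thorax closest to each other.

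Aphids, the prey of the larvae, were the best database hit of 9405 unigenes. These took 3.65% ± 0.627 of the counts in larvae and 0.420% ± 0.141 in pupae (n = 3 each). The share in the head was 0.0515% ± 0.00271, and in the 7 other groups the mean share lay between 0.0207% in the thorax and 0.0442% in eggs. Because these unigenes move with the larval stage, the counts of the comparisons that involve larvae or pupae are also given from a fit without them, an alternative chosen after the data were seen. Gene lists count such unigenes among their members in all comparisons. In that fit the muscle structure list fell from 199 to 161 members and the oxidative phosphorylation list from 175 to 112. The cuticle protein list fell from 198 to 158 and the chemosensory protein list from 16 to 6.

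**Figure D2:**
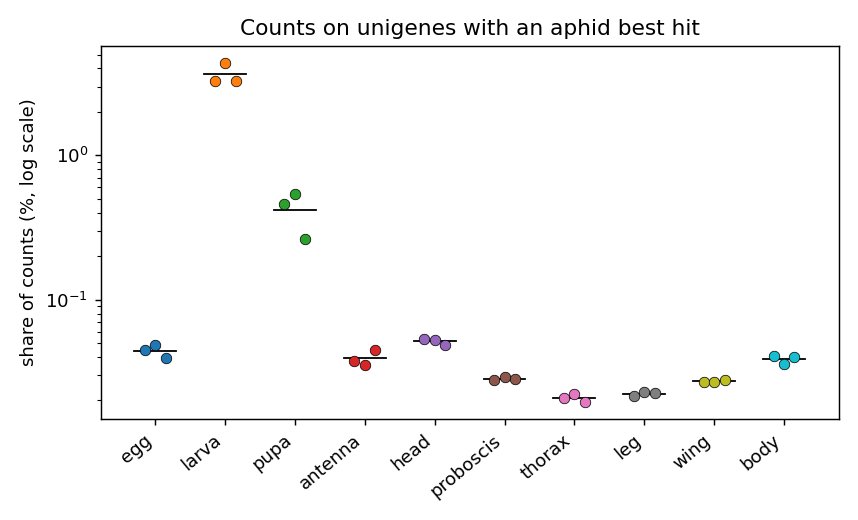
Share of counts on unigenes whose best hit is an aphid or its endosymbiont (vertical axis, percent, log scale) in each of the 30 libraries by group, with a line at the mean of 3 libraries. The 3 larva libraries lie between 3.28% and 4.38% and the 3 pupa libraries between 0.264% and 0.538%.

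The first comparison asked which transcripts differ between larvae and eggs. Larvae had higher levels of storage protein, digestive enzyme and muscle transcripts, and eggs had higher levels of cell cycle transcripts. A unigene annotated as arylphorin subunit C223-like, a hexamerin that insects store in the haemolymph (TRINITY_DN8774_c0_g1), reached 709 ± 112 CPM in larvae with 0 counts in eggs (at least 10956-fold higher). Chymotrypsin-2, a gut protease (TRINITY_DN3656_c0_g1), was at 159 ± 13.5 in larvae with 0 counts in eggs (at least 2460-fold higher). In eggs, cyclin-B, which drives entry into mitosis (TRINITY_DN1443_c0_g1), was at 1254 ± 381 against 12.3 ± 2.34 in larvae (log2 fold change -6.67, SE 0.27, adjusted p = 1.1e-17). Among the 3 egg libraries the chi-square per degree of freedom was 92.4 between replicates 1 and 3, and 41.6 and 58.6 for the 2 other pairs. In all, 11572 unigenes were higher and 6403 lower in larvae. Of the higher ones 3404 were annotated as aphid, and without aphid-annotated unigenes 8027 were higher and 6507 lower.

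Among 31 storage protein unigenes, 31 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 1.0e-12, and adjusted p = 0.046 with an estimated correlation). Of 278 digestive enzyme unigenes, 182 were higher and 15 lower (183 and 15 adjusted over the list alone, adjusted p = 6.6e-09, and adjusted p = 0.044 with an estimated correlation), among them Chymotrypsinogen B (TRINITY_DN3963_c0_g1) at 123 ± 11.4 against 0 counts in eggs. Among 199 muscle structure unigenes, 161 were higher and 2 lower (163 and 2 adjusted over the list alone, adjusted p = 1.0e-12, and adjusted p = 0.046 with an estimated correlation). Of 95 pigment and tanning unigenes, 69 were higher and 3 lower (the same numbers adjusted over the list alone, adjusted p = 3.9e-08, and adjusted p = 0.046 with an estimated correlation). Among 80 haemocyte marker unigenes, 64 were higher and 4 lower (the same numbers adjusted over the list alone, adjusted p = 1.6e-08, and adjusted p = 0.046 with an estimated correlation). Of 186 cytochrome P450 unigenes, 104 were higher and 15 lower (the same numbers adjusted over the list alone, adjusted p = 0.0024, and adjusted p = 0.046 with an estimated correlation). Cytochromes P450 are enzymes that oxidise hormones and foreign compounds. Among 115 odorant-binding protein unigenes, 60 were higher and 2 lower (the same numbers adjusted over the list alone, adjusted p = 2.2e-04, and adjusted p = 0.12 with an estimated correlation), and without aphid-annotated unigenes 57 of 112 were higher and 2 lower (adjusted p = 0.026 with an estimated correlation). Single cuticle transcripts changed in both directions. The pupal cuticle protein Edg-78E (TRINITY_DN3796_c0_g1) was at 531 ± 32.0 in larvae with 0 counts in eggs, while a Cuticle protein 6 unigene (TRINITY_DN15013_c0_g1) was at 55.4 ± 12.2 in eggs with 0 counts in larvae (at least 553-fold lower). Flexible cuticle protein 12 (TRINITY_DN10657_c0_g1) was at 1768 ± 83.4 in larvae and 0.0207 ± 0.0359 in eggs (ratio 85400, 95% counting interval 15300 to 3370000, adjusted p = 1.6e-20), on 1 count in egg replicate 1.

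Of 81 cell cycle and DNA replication unigenes, 16 were higher and 52 lower (the same numbers adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.0021 with an estimated correlation), and without aphid-annotated unigenes 1 of 66 was higher and 53 were lower. Cyclin-A (TRINITY_DN5408_c0_g2) was at 13.1 ± 3.57 in eggs and 0.168 ± 0.0601 in larvae. Among 141 embryonic patterning unigenes, 39 were higher and 56 lower (the same numbers adjusted over the list alone, adjusted p = 0.0052, and adjusted p = 0.12 with an estimated correlation). The median of this list was -0.46 and its mean 0.0804 on the log2 scale, and without aphid-annotated unigenes 19 of 122 were higher and 57 lower (adjusted p = 0.011 with an estimated correlation). The putative bicoid protein, a determinant of the embryo's front end in other flies (TRINITY_DN2000_c0_g1), was at 73.5 ± 32.4 in eggs and 0.0331 ± 0.0573 in larvae (ratio 2220, 95% counting interval 398 to 87700, adjusted p = 1.6e-11), on 1 count in larva replicate 3. Zerknuellt 7 (TRINITY_DN8001_c0_g1), a homeobox gene of the same embryonic cluster, was at 15.6 ± 9.47 in eggs with 0 counts in larvae (at least 155-fold lower). The protein lin-28 homolog, an RNA-binding regulator of developmental timing (TRINITY_DN963_c0_g2), was at 100 ± 43.0 in eggs with 0 counts in larvae (at least 998-fold lower).

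Of 208 ribosomal protein unigenes, 101 were higher and 15 lower (the same numbers adjusted over the list alone, adjusted p = 3.6e-07, and adjusted p = 0.19 with an estimated correlation), but without aphid-annotated unigenes 4 of 112 were higher and 15 lower and the list was not called (adjusted p = 0.86, and adjusted p = 0.98 with an estimated correlation). Among 3429 unigenes annotated as aphid or endosymbiont, 3404 were higher and 10 lower (3404 and 12 adjusted over the list alone, adjusted p = 4.2e-69, and adjusted p = 0.033 with an estimated correlation). The number of aphid-annotated calls depended on the tool, since DESeq2 called 1042 higher and 10 lower. Of 19 yolk and eggshell unigenes, 6 were higher and 5 lower (the same numbers adjusted over the list alone, adjusted p = 0.6, and adjusted p = 0.65 with an estimated correlation), with a median of 0.33 and a mean of 1.02 against a test direction of lower in larvae. With upper quartile scaling, which shifted the median log2 fold change by -0.762, 9409 unigenes were higher and 10151 lower in larvae, so the balance of higher and lower calls depends on the scaling.

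**Figure D3:**
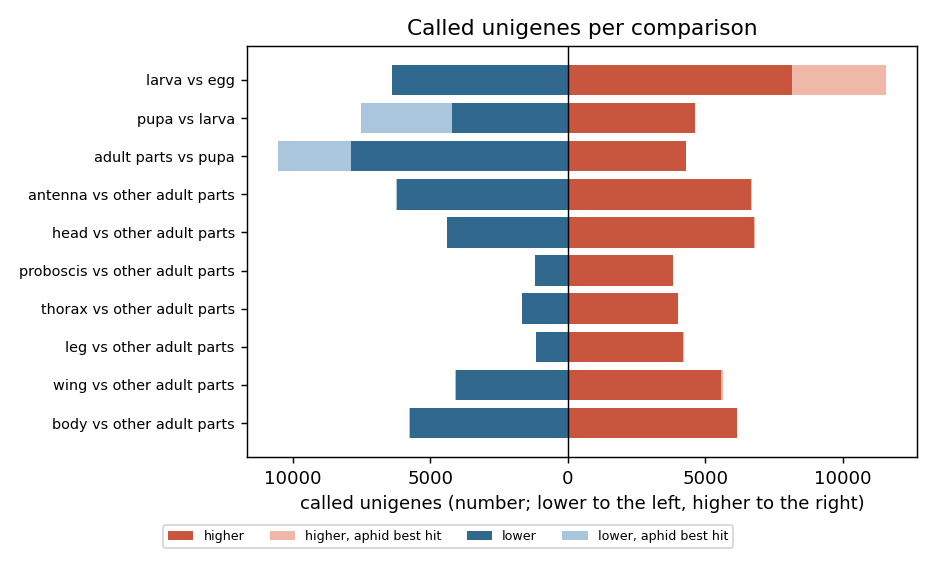
Number of called unigenes (horizontal axis) that were higher (right, red) or lower (left, blue) in the first-named group of each of the 10 comparisons, with lighter shades for unigenes whose best hit is an aphid. Aphid-annotated unigenes made up 3404 of the 11572 unigenes higher in larvae compared with eggs and 3309 of the 7511 lower in pupae compared with larvae.

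The next comparison followed the change from larva to pupa. Transcripts of cytochromes P450 were lower in pupae, and cuticle protein unigenes changed in both directions. The lists of digestive enzymes and storage proteins were lower with the preset correlation, and with the estimated one only when aphid-annotated unigenes were left out. Maltase A3, which splits sugars in the gut (TRINITY_DN28022_c0_g1), was at 496 ± 70.8 in larvae with 0 counts in pupae (at least 7216-fold lower). Larval cuticle protein 4-like (TRINITY_DN3796_c0_g2) was at 729 ± 96.9 in larvae and 0.0694 ± 0.00873 in pupae (ratio 10500, 95% counting interval 3590 to 50900, adjusted p = 8.5e-19), on 3 counts in pupae. In the other direction, a unigene annotated as 20-hydroxyecdysone protein, named after the moulting hormone (TRINITY_DN11975_c0_g1), was at 9597 ± 1494 in pupae and 258 ± 37.4 in larvae (log2 fold change 5.22, SE 0.48, adjusted p = 6.8e-10). In all, 4632 unigenes were higher and 7511 lower in pupae. Of the lower ones 3309 were annotated as aphid, and without aphid-annotated unigenes 4017 were higher and 4435 lower.

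Among the 278 digestive enzyme unigenes, 22 were higher and 150 lower (24 and 151 adjusted over the list alone, adjusted p = 2.6e-09, and adjusted p = 0.077 with an estimated correlation), and without aphid-annotated unigenes 21 of 257 were higher and 137 lower (adjusted p = 0.0099 with an estimated correlation). Maltase A2 (TRINITY_DN12899_c0_g1) was at 139 ± 8.57 in larvae with 0 counts in pupae. Of the 31 storage protein unigenes, 0 were higher and 29 lower (the same numbers adjusted over the list alone, adjusted p = 2.6e-09, and adjusted p = 0.1 with an estimated correlation), and without aphid-annotated unigenes 0 of 31 were higher and 30 lower (adjusted p = 0.013 with an estimated correlation). LSP1gamma (TRINITY_DN6816_c0_g1) was at 0.182 ± 0.0267 in pupae against 69.0 ± 1.55 in larvae. Among the 186 cytochrome P450 unigenes, 9 were higher and 102 lower (9 and 103 adjusted over the list alone, adjusted p = 2.4e-06, and adjusted p = 0.013 with an estimated correlation). Of the 95 pigment and tanning unigenes, 6 were higher and 67 lower (6 and 69 adjusted over the list alone, adjusted p = 3.4e-09, and adjusted p = 0.056 with an estimated correlation), and without aphid-annotated unigenes 6 of 87 were higher and 59 lower (adjusted p = 0.0054 with an estimated correlation). Phenoloxidase 2, an enzyme of melanin formation (TRINITY_DN26966_c0_g1), was at 9.83 ± 0.942 in larvae with 0 counts in pupae, whereas phenoloxidase-activating factor 2-like (TRINITY_DN4199_c0_g2) was at 13.98 ± 2.32 in pupae with 0 counts in larvae. Summed with the other unigenes of the same annotation, the latter had a log2 fold change of -1.32 in place of 10.45. Among the 199 muscle structure unigenes, 10 were higher and 135 lower (11 and 135 adjusted over the list alone, adjusted p = 4.0e-09, and adjusted p = 0.13 with an estimated correlation). Troponin C-like (TRINITY_DN12175_c0_g1) was at 0.934 ± 0.324 in pupae against 126 ± 12.99 in larvae. Of the 208 ribosomal protein unigenes, 0 were higher and 97 lower (0 and 99 adjusted over the list alone, adjusted p = 4.7e-18, and adjusted p = 0.069 with an estimated correlation), and without aphid-annotated unigenes 0 of 112 were higher and 5 lower. Among the 3429 unigenes annotated as aphid or endosymbiont, 6 were higher and 3309 lower (7 and 3330 adjusted over the list alone, adjusted p = 5.2e-111, and adjusted p = 0.0041 with an estimated correlation), and DESeq2 called 4 higher and 702 lower.

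Of 198 cuticle protein unigenes, 41 were higher and 89 lower (41 and 91 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.42 with an estimated correlation), and without aphid-annotated unigenes 40 of 158 were higher and 50 lower (adjusted p = 0.18, and adjusted p = 0.8 with an estimated correlation). A Cuticle protein 6 unigene (TRINITY_DN41277_c0_g1) was at 207 ± 45.3 in pupae with 0 counts in larvae (at least 2070-fold higher), and cuticle protein 7 (TRINITY_DN12631_c0_g1) was at 206 ± 73.5 in pupae and 0.0684 ± 0.0593 in larvae. Among 66 chitin metabolism unigenes, 19 were higher and 23 lower (20 and 24 adjusted over the list alone, adjusted p = 0.29, and adjusted p = 0.56 with an estimated correlation). Endochitinase, which breaks down chitin (TRINITY_DN8546_c0_g1), was at 0.234 ± 0.0686 in pupae against 761 ± 48.5 in larvae. Of 35 ecdysone pathway unigenes, 11 were higher and 12 lower (11 and 13 adjusted over the list alone, adjusted p = 0.76, and adjusted p = 0.83 with an estimated correlation). This list had a median of 0.0351 and a mean of -0.784, its test direction turned with members matched in Swiss-Prot descriptions alone, and without aphid-annotated unigenes 10 of 25 were higher and 4 lower (adjusted p = 0.012, and adjusted p = 0.071 with an estimated correlation). Ecdysteroid UDP-glucosyltransferase, which inactivates moulting hormones in other insects (TRINITY_DN13067_c0_g2), was at 0.156 ± 0.0693 in pupae against 46.6 ± 10.8 in larvae. Among the 141 embryonic patterning unigenes, 37 were higher and 29 lower (38 and 29 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.21 with an estimated correlation), with a median of 0.63 and a mean of -0.0420. Without aphid-annotated unigenes 33 of 122 were higher and 10 lower (adjusted p = 0.017 with an estimated correlation), and DESeq2 called 28 higher and 15 lower among all members. Upper quartile scaling, which shifted the median log2 fold change by 0.479, called 7855 unigenes higher and 6543 lower in pupae.

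The third comparison set the mean of the 7 adult parts against pupae. Adult parts had higher levels of circadian clock and cytochrome P450 transcripts, and pupae had higher levels of cell cycle transcripts. The storage protein list was higher in pupae with the preset correlation, and with the estimated one only when aphid-annotated unigenes were left out. The unigene annotated as 20-hydroxyecdysone protein (TRINITY_DN11975_c0_g1) was at 9597 ± 1494 in pupae and at most 2.03 ± 0.449 in the thorax (log2 fold change -12.79, SE 0.28, adjusted p = 2.8e-24). Cuticle protein 6 (TRINITY_DN22747_c0_g1) was at 4773 ± 1239 in pupae and at most 0.882 ± 0.379 in the thorax. Adult cuticle protein 1 (TRINITY_DN3281_c0_g1) was at 0.388 ± 0.0374 in pupae and ranged from 60.1 ± 5.50 in the head to 1429 ± 97.5 in the wing (log2 fold change 9.53, SE 0.28, adjusted p = 2.1e-21). In all, 4306 unigenes were higher and 10546 lower in adult parts. Of the lower ones 2666 were annotated as aphid, and without aphid-annotated unigenes 4886 were higher and 7043 lower.

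Of 20 circadian clock unigenes, 14 were higher and 2 lower (the same numbers adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.0016 with an estimated correlation). Of these 20 unigenes, 16 are annotated as period or timeless, so the members of this list are not 20 separate genes. Among the 186 cytochrome P450 unigenes, 82 were higher and 36 lower (the same numbers adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.0016 with an estimated correlation). Of the 81 cell cycle and DNA replication unigenes, 0 were higher and 57 lower (the same numbers adjusted over the list alone, adjusted p = 2.2e-08, and adjusted p = 0.004 with an estimated correlation), such as the mitotic kinase polo (TRINITY_DN304_c0_g1) at 19.9 ± 1.92 in pupae against at most 6.14 ± 1.82 in the body. Among the 31 storage protein unigenes, 0 were higher and 29 lower (the same numbers adjusted over the list alone, adjusted p = 2.5e-10, and adjusted p = 0.11 with an estimated correlation), and without aphid-annotated unigenes 0 of 31 were higher and 29 lower (adjusted p = 0.041 with an estimated correlation). Of the 35 ecdysone pathway unigenes, 2 were higher and 22 lower (the same numbers adjusted over the list alone, adjusted p = 1.5e-04, and adjusted p = 0.1 with an estimated correlation), and without aphid-annotated unigenes 2 of 25 were higher and 12 lower (adjusted p = 0.0076 with an estimated correlation). Among 175 oxidative phosphorylation unigenes, 69 were higher and 68 lower (69 and 69 adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.19 with an estimated correlation), with a median of 0.39 and a mean of -0.73. Without aphid-annotated unigenes 70 of 112 were higher and 8 lower (adjusted p = 0.040 with an estimated correlation). Cytochrome c oxidase subunit 4 isoform 1 (TRINITY_DN424_c0_g1) was at 98.3 ± 20.1 in pupae and 3906 ± 266 in the thorax. Of the 199 muscle structure unigenes, 33 were higher and 52 lower (33 and 51 adjusted over the list alone, adjusted p = 0.2, and adjusted p = 0.78 with an estimated correlation), with a median of 0.16 and a mean of -0.61, and without aphid-annotated unigenes 38 of 161 were higher and 16 lower (adjusted p = 0.016, and adjusted p = 0.6 with an estimated correlation). Among the 3429 unigenes annotated as aphid or endosymbiont, 9 were higher and 2666 lower (9 and 2678 adjusted over the list alone, adjusted p = 2.9e-12, and adjusted p = 0.3 with an estimated correlation), and DESeq2 called 9 higher and 741 lower.

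Of the 198 cuticle protein unigenes, 37 were higher and 90 lower (37 and 91 adjusted over the list alone, adjusted p = 0.55, and adjusted p = 0.86 with an estimated correlation). Larval cuticle protein A2B (TRINITY_DN15256_c0_g1) was at 329 ± 116 in pupae and at most 0.195 ± 0.00938 in the proboscis, and Retinin, a protein of the corneal surface of the fly eye (TRINITY_DN6130_c0_g1), was at 284 ± 33.3 in pupae and at most 0.101 ± 0.0621 in the head. Among 37 phototransduction unigenes, 4 were higher and 17 lower (the same numbers adjusted over the list alone, adjusted p = 0.73, and adjusted p = 0.86 with an estimated correlation). The contrast averages log levels over the parts, so a transcript abundant in 1 part can be lower in it. Inactivation-no-after-potential D protein (TRINITY_DN12162_c0_g1) had a log2 fold change of -3.99 although it reached 6038 ± 272 in the head against 89.2 ± 13.3 in pupae.

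Each adult part was then compared with the mean of the 6 other parts. In the antenna, olfactory transcripts stood out, with higher levels of nearly every odorant and ionotropic receptor unigene and lower levels of muscle transcripts. OBP13, an odorant-binding protein (TRINITY_DN19778_c1_g1), was at 1947 ± 133 in the antenna, and its next highest part was 2.17 ± 0.898 in the wing (log2 fold change 12.07, SE 0.15, adjusted p = 4.0e-29). Sensory neuron membrane protein 1, known from pheromone-sensing neurons (TRINITY_DN11090_c0_g1), was at 1149 ± 89.6 and at most 1.74 ± 1.48 in the wing. Esterase-5B-like (TRINITY_DN286_c0_g1) was at 2418 ± 199 and at most 3.37 ± 3.00 in the wing. The muscle protein titin-like (TRINITY_DN395_c1_g1) was at 2.54 ± 0.232 in the antenna and 4166 ± 285 in the leg (log2 fold change -8.23, SE 0.37, adjusted p = 4.2e-17). In all, 6697 unigenes were higher and 6235 lower in the antenna.

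Of 42 odorant receptor unigenes, 39 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 3.6e-27, and adjusted p = 0.0026 with an estimated correlation), and DESeq2 called 18 higher and 0 lower. The putative odorant receptor OR23 (TRINITY_DN6001_c0_g1) was at 35.7 ± 3.39 in the antenna with 0 counts in the 6 other parts (at least 386-fold higher), and OR35 (TRINITY_DN1866_c0_g1) was at 36.3 ± 2.88 against at most 0.0398 ± 0.0690 in the thorax. Among 46 ionotropic receptor unigenes, 45 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 5.7e-31, and adjusted p = 0.0027 with an estimated correlation), and DESeq2 called 29 higher and 0 lower. The putative ionotropic receptor IR9 (TRINITY_DN6598_c0_g1) was at 32.9 ± 4.55 against at most 0.0674 ± 0.117 in the wing. Of 3 sensory neuron membrane protein unigenes, 3 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 0.0069, and adjusted p = 0.036 with an estimated correlation). Among the 115 odorant-binding protein unigenes, 41 were higher and 27 lower (the same numbers adjusted over the list alone, adjusted p = 0.062, and adjusted p = 0.5 with an estimated correlation), with a median of -0.27 and a mean of 1.244, and without aphid-annotated unigenes 41 of 112 were higher and 28 lower (adjusted p = 0.038, and adjusted p = 0.43 with an estimated correlation). OBP23 (TRINITY_DN9564_c0_g1) was at 1776 ± 129 against at most 1.88 ± 1.75 in the wing. Of 16 chemosensory protein unigenes, 7 were higher and 1 lower (the same numbers adjusted over the list alone, adjusted p = 0.29, and adjusted p = 0.65 with an estimated correlation), and DESeq2 called 4 higher and 1 lower. Among 75 carboxylesterase unigenes, 36 were higher and 9 lower (the same numbers adjusted over the list alone, adjusted p = 3.4e-05, and adjusted p = 0.015 with an estimated correlation). Of 50 glutathione S-transferase unigenes, 17 were higher and 6 lower (the same numbers adjusted over the list alone, adjusted p = 0.17, and adjusted p = 0.6 with an estimated correlation). Among 186 cytochrome P450 unigenes, 68 were higher and 20 lower (the same numbers adjusted over the list alone, adjusted p = 0.0059, and adjusted p = 0.039 with an estimated correlation). A probable cytochrome P450 308a1 (TRINITY_DN4465_c0_g1) was at 82.5 ± 9.40 against at most 1.12 ± 0.155 in the leg. Of 98 testis and axoneme unigenes, 50 were higher and 5 lower (the same numbers adjusted over the list alone, adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation). Tektin-1, a protein of ciliary microtubules (TRINITY_DN8217_c0_g1), was at 91.5 ± 15.3 against at most 13.8 ± 4.92 in the body. Among 199 muscle structure unigenes, 3 were higher and 127 lower (the same numbers adjusted over the list alone, adjusted p = 4.9e-15, and adjusted p = 0.036 with an estimated correlation).

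In the head, transcripts of the visual cascade were higher than in the mean of the other parts and circadian clock transcripts were lower. Opsin Rh1, the main visual pigment of fly photoreceptors (TRINITY_DN2341_c0_g1), was at 2007 ± 35.9 in the head and at most 3.10 ± 0.944 in the proboscis (log2 fold change 11.95, SE 0.16, adjusted p = 7.2e-29). Phosrestin-2, an arrestin (TRINITY_DN22540_c0_g3), was at 3801 ± 201 and at most 3.50 ± 0.890 in the proboscis, and inactivation-no-after-potential D protein, a scaffold of the same cascade (TRINITY_DN12162_c0_g1), was at 6038 ± 272 and at most 8.14 ± 1.84 in the proboscis. The clock component timeless (TRINITY_DN813_c0_g1) was at 177 ± 11.7 in the head and 2854 ± 188 in the wing (log2 fold change -2.38, SE 0.16, adjusted p = 1.7e-13). In all, 6789 unigenes were higher and 4410 lower in the head.

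Of the 37 phototransduction unigenes, 28 were higher and 3 lower (the same numbers adjusted over the list alone, adjusted p = 1.9e-14, and adjusted p = 0.0071 with an estimated correlation). Transient receptor potential protein-like, a channel (TRINITY_DN74643_c0_g1), was at 99.2 ± 3.50 against at most 0.134 ± 0.156 in the proboscis. Among 30 neuropeptide signalling unigenes, 23 were higher and 3 lower (the same numbers adjusted over the list alone, adjusted p = 3.2e-07, and adjusted p = 0.079 with an estimated correlation). Callisulfakinin (TRINITY_DN13882_c0_g1) was at 31.0 ± 2.93 against at most 0.0960 ± 0.0978 in the proboscis, while tachykinins (TRINITY_DN7039_c0_g1) were at 26.3 ± 3.10 against 20.4 ± 4.03 in the body. Of 64 synapse unigenes, 19 were higher and 11 lower (the same numbers adjusted over the list alone, adjusted p = 0.35, and adjusted p = 0.52 with an estimated correlation), with a median of -0.0891 and a mean of 0.854. Vesicular glutamate transporter 1 (TRINITY_DN19679_c0_g1) was at 19.6 ± 3.24 against at most 1.72 ± 0.668 in the thorax. Among the 20 circadian clock unigenes, 0 were higher and 13 lower (the same numbers adjusted over the list alone, adjusted p = 1.9e-06, and adjusted p = 0.0074 with an estimated correlation). The period protein (TRINITY_DN11608_c0_g1) was at 42.7 ± 3.23 against 539.7 ± 21.0 in the antenna. Of 31 storage protein unigenes, 28 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 1.1e-08, and adjusted p = 0.15 with an estimated correlation). Among 52 fat body marker unigenes, 25 were higher and 2 lower (the same numbers adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.37 with an estimated correlation), a list that shares members with the storage proteins. Of 186 cytochrome P450 unigenes, 24 were higher and 72 lower (25 and 74 adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.015 with an estimated correlation). Among 199 muscle structure unigenes, 2 were higher and 86 lower (the same numbers adjusted over the list alone, adjusted p = 4.3e-07, and adjusted p = 0.2 with an estimated correlation). Among the largest decreases, farnesol dehydrogenase-like (TRINITY_DN4890_c0_g1) was at 0.224 ± 0.144 in the head and 373 ± 9.51 in the proboscis.

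In the proboscis, taste and odorant-binding transcripts and muscle transcripts were higher than in the mean of the other parts. Of the 199 muscle structure unigenes, 144 were also higher in the thorax and 142 in the leg, each against the mean of its other parts. OBP34 (TRINITY_DN9237_c0_g1) was at 248 ± 27.3 in the proboscis and at most 0.146 ± 0.126 in the leg (adjusted p = 1.8e-22). A unigene annotated as gustatory receptor for sugar taste 64f (TRINITY_DN73441_c0_g1) was at 11 ± 1.03 and at most 3.64 ± 1.02 in the leg. Homeotic protein proboscipedia, which specifies mouthparts in other insects (TRINITY_DN10941_c0_g2), was at 102 ± 8.24 and at most 11.8 ± 1.29 in the antenna. Serine protease 1 (TRINITY_DN5938_c0_g1) was at 1021 ± 94.1 and at most 62.2 ± 4.71 in the leg. In all, 3839 unigenes were higher and 1199 lower in the proboscis.

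Of 14 gustatory receptor unigenes, 8 were higher and 0 lower (9 and 0 adjusted over the list alone, adjusted p = 7.6e-08, and adjusted p = 1.2e-04 with an estimated correlation). Among the 115 odorant-binding protein unigenes, 44 were higher and 6 lower (the same numbers adjusted over the list alone, adjusted p = 1.4e-12, and adjusted p = 0.0055 with an estimated correlation). OBP26 (TRINITY_DN56762_c0_g1) was at 235 ± 30.4 against at most 2.18 ± 0.379 in the leg. Of the 16 chemosensory protein unigenes, 3 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 0.53, and adjusted p = 0.83 with an estimated correlation), with a median of -0.21 and a mean of 0.0981. Among the 199 muscle structure unigenes, 135 were higher and 1 lower (136 and 1 adjusted over the list alone, adjusted p = 7.4e-31, and adjusted p = 0.0037 with an estimated correlation). The fit without aphid-annotated unigenes had 135 of 161 muscle structure unigenes higher and 1 lower. Of the 186 cytochrome P450 unigenes, 76 were higher and 11 lower (77 and 13 adjusted over the list alone, adjusted p = 3.5e-11, and adjusted p = 1.2e-04 with an estimated correlation), although Cytochrome P450 4g15 (TRINITY_DN11177_c0_g1) had 1 of the 4 largest decreases, at 5.16 ± 0.938 in the proboscis against 3221 ± 632 in the body. Among the 278 digestive enzyme unigenes, 37 were higher and 14 lower (the same numbers adjusted over the list alone, adjusted p = 0.45, and adjusted p = 0.9 with an estimated correlation), with a median of -0.28 and a mean of -0.23 against a test direction of higher. Carboxypeptidase B (TRINITY_DN30051_c0_g1) was at 16.8 ± 1.56 against at most 0.0501 ± 0.0487 in the body.

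In the thorax, which holds the flight muscles, muscle and respiratory chain transcripts were higher than in the mean of the other parts. Flightin, a protein of the flight muscle thick filament (TRINITY_DN21917_c0_g2), was at 19966 ± 4797 in the thorax and at most 37.6 ± 36.8 in the body (log2 fold change 11.13, SE 0.25, adjusted p = 1.5e-23). Troponin C-like, a calcium sensor of muscle (TRINITY_DN6618_c0_g1), was at 21936 ± 10878 and at most 52.9 ± 1.14 in the proboscis. ATP synthase subunit alpha (TRINITY_DN38873_c0_g1) was at 20806 ± 2151 and 6468 ± 251 in the proboscis (log2 fold change 3.46, SE 0.08, adjusted p = 9.2e-23). The 10 most abundant unigenes took 37.1% ± 0.672 of the counts in the thorax, the highest share of the 10 groups. Thorax replicate 3 differed from replicates 1 and 2 (chi-square per degree of freedom 83.4 and 104) more than these did from each other (7.31). Troponin C-like was at 34489 in it and at 16060 and 15260 in the 2 others. In all, 4017 unigenes were higher and 1670 lower in the thorax.

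Of the 199 muscle structure unigenes, 144 were higher and 2 lower (the same numbers adjusted over the list alone, adjusted p = 5.1e-32, and adjusted p = 0.0033 with an estimated correlation). Among the 175 oxidative phosphorylation unigenes, 84 were higher and 1 lower (85 and 1 adjusted over the list alone, adjusted p = 4.3e-28, and adjusted p = 0.0033 with an estimated correlation). In the fit without aphid-annotated unigenes, 143 of 161 muscle structure unigenes were higher and 2 lower. For oxidative phosphorylation that fit had 86 of 112 higher and 0 lower. Cytochrome c oxidase subunit 7A1 (TRINITY_DN34179_c0_g1) was at 108 ± 1.92 against at most 34.6 ± 1.33 in the proboscis. Of 31 storage protein unigenes, 17 were higher and 0 lower (18 and 0 adjusted over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.45 with an estimated correlation). Among 83 heat shock protein unigenes, 16 were higher and 0 lower (17 and 0 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.58 with an estimated correlation). Of the 20 circadian clock unigenes, 0 were higher and 7 lower (the same numbers adjusted over the list alone, adjusted p = 2.2e-04, and adjusted p = 0.024 with an estimated correlation), and DESeq2 called 0 higher and 4 lower. Among unigenes outside these lists, muscle M-line assembly protein unc-89 (TRINITY_DN14973_c0_g1) was at 919.7 ± 570.5 (1578 in replicate 3) against at most 1.503 ± 1.85 in the body, and Peritrophin-1, a chitin-binding protein of the gut lining in other insects (TRINITY_DN15101_c0_g1), was at 803 ± 73.3 against 135 ± 121 in the body. Protein takeout-like (TRINITY_DN10165_c0_g1) was lower, at 3.74 ± 1.05 against 347 ± 31.5 in the wing.

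In the leg, muscle transcripts were higher than in the mean of the other parts, together with 7 gustatory receptor unigenes. Trypsin beta (TRINITY_DN2625_c0_g1) was at 1360.4 ± 58.9 in the leg and at most 21.0 ± 18.0 in the wing (log2 fold change 10.74, SE 0.30, adjusted p = 9.4e-21). Phospholipase A1, a lipase (TRINITY_DN1585_c0_g1), was at 772 ± 123 and at most 14.5 ± 13.6 in the wing. A unigene annotated as troponin C-like (TRINITY_DN12175_c0_g1) was at 134 ± 8.44 and at most 22.3 ± 3.77 in the body. In all, 4211 unigenes were higher and 1174 lower in the leg.

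Among 199 muscle structure unigenes, 142 were higher and 1 lower (144 and 1 adjusted over the list alone, adjusted p = 2.0e-47, and adjusted p = 5.6e-04 with an estimated correlation). The fit without aphid-annotated unigenes had 140 of 161 higher and 1 lower. Of the 14 gustatory receptor unigenes, 7 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 0.0069, and adjusted p = 0.035 with an estimated correlation), and without aphid-annotated unigenes the list's adjusted p = 0.061 with an estimated correlation. The putative gustatory receptor 77a (TRINITY_DN17378_c0_g1) was at 5.84 ± 1.29 in the leg, below the 93.2 ± 8.72 in the antenna. Among 115 odorant-binding protein unigenes, 28 were higher and 14 lower (28 and 16 adjusted over the list alone, adjusted p = 0.078, and adjusted p = 0.62 with an estimated correlation), with a median of -0.33 and a mean of 0.512. Its largest increase was a unigene annotated as phosphatidylethanolamine-binding protein homolog (TRINITY_DN10519_c0_g1), at 727 ± 57.9 against at most 15 ± 13.4 in the wing. Of the 16 chemosensory protein unigenes, 1 were higher and 1 lower (the same numbers adjusted over the list alone, adjusted p = 0.99, and adjusted p = 0.99 with an estimated correlation), with a median of -0.16 and a mean of -0.0920, and the test direction turned with both other scalings. Among the 198 cuticle protein unigenes, 36 were higher and 6 lower (35 and 6 adjusted over the list alone, adjusted p = 0.29, and adjusted p = 0.91 with an estimated correlation), with a median of 0 and a mean of 0.0142. Larval cuticle protein A3A (TRINITY_DN6567_c0_g1) was at 196 ± 47.3 against at most 117 ± 14.7 in the wing. Among the decreases, calexcitin-2, a calcium-binding protein (TRINITY_DN22744_c0_g1), was at 5.01 ± 1.10 against 745 ± 52.4 in the head.

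In the wing, clock transcripts were higher than in the mean of the other parts, as were single enzymes of cuticle tanning and chitin modification. Cytochrome P450 transcripts were lower. Tyrosine 3-monooxygenase, the first enzyme of dopamine and melanin synthesis (TRINITY_DN6512_c0_g1), was at 5508 ± 684 in the wing and 949 ± 47.1 in the leg (log2 fold change 4.75, SE 0.15, adjusted p = 3.0e-20). Chitin deacetylase 1 (TRINITY_DN19594_c0_g1) was at 2030.3 ± 47.6 and 355 ± 10.5 in the leg. The homeobox protein Optix (TRINITY_DN34408_c0_g1) was at 149 ± 12.4 and 24.2 ± 1.19 in the proboscis. OBP1 (TRINITY_DN6803_c0_g1) was at 4889 ± 101 and 137 ± 13.2 in the leg. In all, 5651 unigenes were higher and 4087 lower in the wing.

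Of 20 circadian clock unigenes, 14 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 6.6e-08, and adjusted p = 0.0015 with an estimated correlation). The period protein (TRINITY_DN11608_c0_g1) was at 498 ± 30.3 in the wing, below the 539.7 ± 21.0 in the antenna. Cryptochrome-1 (TRINITY_DN3722_c0_g1) was not among the 14 called members. It was at 121.7 ± 9.02 in the wing, below the 167.4 ± 14.1 in the antenna. Timeless (TRINITY_DN813_c0_g1) was highest in the wing, at 2854 ± 188. Among the 186 cytochrome P450 unigenes, 18 were higher and 78 lower (18 and 79 adjusted over the list alone, adjusted p = 1.4e-08, and adjusted p = 0.0015 with an estimated correlation). Of the 175 oxidative phosphorylation unigenes, 11 were higher and 66 lower (the same numbers adjusted over the list alone, adjusted p = 1.0e-13, and adjusted p = 0.07 with an estimated correlation). Among 198 cuticle protein unigenes, 53 were higher and 9 lower (53 and 8 adjusted over the list alone, adjusted p = 0.063, and adjusted p = 0.66 with an estimated correlation), and without aphid-annotated unigenes 48 of 158 were higher and 9 lower (adjusted p = 0.0072, and adjusted p = 0.69 with an estimated correlation). Pupal cuticle protein Edg-78E-like (TRINITY_DN1493_c0_g1) was at 11.3 ± 0.913 against at most 0.770 ± 0.447 in the body. Of the 66 chitin metabolism unigenes, 21 were higher and 8 lower (21 and 9 adjusted over the list alone, adjusted p = 0.057, and adjusted p = 0.61 with an estimated correlation), with a median of 0 and a mean of 0.293, and without aphid-annotated unigenes 21 of 54 were higher and 10 lower (adjusted p = 0.0053, and adjusted p = 0.22 with an estimated correlation). Among the 95 pigment and tanning unigenes, 22 were higher and 21 lower (the same numbers adjusted over the list alone, adjusted p = 0.75, and adjusted p = 0.91 with an estimated correlation), with a median of -0.27 and a mean of -0.26 against a test direction of higher. Laccase-1, an oxidase of cuticle tanning (TRINITY_DN984_c0_g1), was at 286 ± 48.7 against 39.8 ± 0.643 in the body. Of 16 chemosensory protein unigenes, 4 were higher and 1 lower (the same numbers adjusted over the list alone, adjusted p = 0.46, and adjusted p = 0.71 with an estimated correlation). CSP2 (TRINITY_DN1623_c0_g1) was at 2862 ± 82.4 against 1377 ± 92.3 in the proboscis. Among the 30 neuropeptide signalling unigenes, 2 were higher and 17 lower (2 and 18 adjusted over the list alone, adjusted p = 4.6e-05, and adjusted p = 0.15 with an estimated correlation). Of the 14 gustatory receptor unigenes, 0 were higher and 1 lower (the same numbers adjusted over the list alone, adjusted p = 0.5, and adjusted p = 0.66 with an estimated correlation), and DESeq2 called 0 higher and 2 lower. Glycine receptor subunit alpha-4 (TRINITY_DN36622_c0_g1) was at 0.128 ± 0.0640 in the wing against 504 ± 44.7 in the head.

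In the body, cell cycle, juvenile hormone pathway and cytochrome P450 transcripts were higher than in the mean of the 6 other parts. The lists of testis and axoneme, digestive enzyme and fat body unigenes were higher with the preset correlation but not with the estimated one, and yolk and eggshell unigenes changed in both directions. Sialidase-like (TRINITY_DN8040_c0_g1) was at 2727 ± 443 in the body and at most 0.249 ± 0.174 in the leg (log2 fold change 14.19, SE 0.21, adjusted p = 4.4e-27). Maltase A3 (TRINITY_DN1135_c1_g1) was at 1102 ± 102 and at most 0.987 ± 0.431 in the leg, and trypsin (TRINITY_DN2007_c0_g1) was at 324 ± 34.2 and at most 0.103 ± 0.109 in the leg. Cilia- and flagella-associated protein 45, a protein of the axoneme (TRINITY_DN91_c0_g1), was at 11.6 ± 1.73 with 0 counts in the 6 other parts (at least 124-fold higher). Body replicate 2 differed from replicates 1 and 3 (chi-square per degree of freedom 70.2 and 75.1) more than these did from each other (27.7). In all, 6156 unigenes were higher and 5762 lower in the body.

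Among the 98 testis and axoneme unigenes, 71 were higher and 7 lower (73 and 8 adjusted over the list alone, adjusted p = 4.1e-16, and adjusted p = 0.17 with an estimated correlation). Of 278 digestive enzyme unigenes, 118 were higher and 29 lower (119 and 29 adjusted over the list alone, adjusted p = 2.8e-06, and adjusted p = 0.24 with an estimated correlation). Among the 31 storage protein unigenes, 29 were higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 4.5e-12, and adjusted p = 0.22 with an estimated correlation). Of the 52 fat body marker unigenes, 37 were higher and 5 lower (38 and 5 adjusted over the list alone, adjusted p = 1.4e-07, and adjusted p = 0.24 with an estimated correlation). Among the 80 haemocyte marker unigenes, 53 were higher and 3 lower (the same numbers adjusted over the list alone, adjusted p = 1.6e-06, and adjusted p = 0.24 with an estimated correlation). Of 73 immunity unigenes, 36 were higher and 11 lower (the same numbers adjusted over the list alone, adjusted p = 0.002, and adjusted p = 0.33 with an estimated correlation). Peptidoglycan-recognition protein LB-like (TRINITY_DN5460_c0_g1) was at 122 ± 24.8 against at most 31.5 ± 1.15 in the thorax. Among the 81 cell cycle and DNA replication unigenes, 38 were higher and 2 lower (39 and 2 adjusted over the list alone, adjusted p = 3.2e-06, and adjusted p = 0.017 with an estimated correlation). The ribonucleoside-diphosphate reductase large subunit, an enzyme that makes DNA precursors (TRINITY_DN34676_c0_g1), was at 64.9 ± 39.1 against at most 0.353 ± 0.136 in the head. Of 31 juvenile hormone pathway unigenes, 18 were higher and 2 lower (19 and 2 adjusted over the list alone, adjusted p = 2.4e-05, and adjusted p = 0.015 with an estimated correlation). Among 186 cytochrome P450 unigenes, 87 were higher and 18 lower (the same numbers adjusted over the list alone, adjusted p = 2.8e-06, and adjusted p = 0.017 with an estimated correlation). Of the 19 yolk and eggshell unigenes, 4 were higher and 4 lower (the same numbers adjusted over the list alone, adjusted p = 0.87, and adjusted p = 0.88 with an estimated correlation). Chorion peroxidase-like (TRINITY_DN15326_c0_g1) was at 233 ± 71.8 against 168 ± 24.8 in the wing. Upper quartile scaling, which shifted the median log2 fold change by -0.302, called 5068 unigenes higher and 7280 lower in the body.

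A unigene was called specific to a group when it was at least 2-fold higher than in each of the 9 other groups. Larvae had 4727 such unigenes, of which 3305 were annotated as aphid, and 1410 in the fit without aphid-annotated unigenes. Eggs had 2462, heads 2452, antennae 2318, the body 1093, wings 1030, pupae 651, the thorax 444, the proboscis 245 and legs 228. In eggs the most abundant with an informative annotation was zinc finger protein on ecdysone puffs (TRINITY_DN7079_c0_g1) at 15435 ± 584 against 4356 ± 144 in pupae. Larvae had larval serum protein 1 beta chain-like (TRINITY_DN3808_c0_g1) at 18050 ± 4308 against 6310.4 ± 1062 in pupae, and the basement membrane Collagen alpha-1(IV) chain (TRINITY_DN8073_c0_g1) at 8178 ± 578 against 589.5 ± 762 in eggs. Among those of pupae was cuticle protein-like (TRINITY_DN19588_c0_g1) at 3162 ± 658 against 1.87 ± 0.822 in the thorax. For the antenna, CSP6 (TRINITY_DN12413_c0_g1) was at 10816 ± 445 against 10.5 ± 9.61 in the wing, and OBP12 (TRINITY_DN6902_c0_g1) at 6719 ± 518 against 7.25 ± 2.98 in the wing. For the head, complexin, which regulates synaptic vesicle release (TRINITY_DN19553_c0_g2), was at 14804 ± 1243 against 2154 ± 257 in the antenna.

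Among the unigenes specific to the proboscis, OBP32 (TRINITY_DN17915_c0_g1) was at 1744 ± 128 against 822 ± 31.5 in the leg. Those specific to the thorax included mitochondrially encoded NADH dehydrogenase subunit 1 (TRINITY_DN4656_c0_g1) at 149640 ± 63720 (79182 in replicate 3) against 33812 ± 1902 in the proboscis, and troponin I (TRINITY_DN6273_c0_g1) at 23896 ± 2716 against 8210.4 ± 1157 in the leg. Those of the leg included muscle-specific protein 20 (TRINITY_DN10728_c0_g1) at 2058 ± 242 against 747 ± 46.8 in larvae. The wing had the cuticle protein Cpr97Ea (TRINITY_DN5653_c0_g1) at 15718 ± 296 against 1940.5 ± 87.6 in the leg. The body had phosphoenolpyruvate carboxykinase, an enzyme of glucose synthesis (TRINITY_DN2129_c0_g1), at 3531 ± 1329 against 817 ± 179 in larvae.

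**Figure D4:**
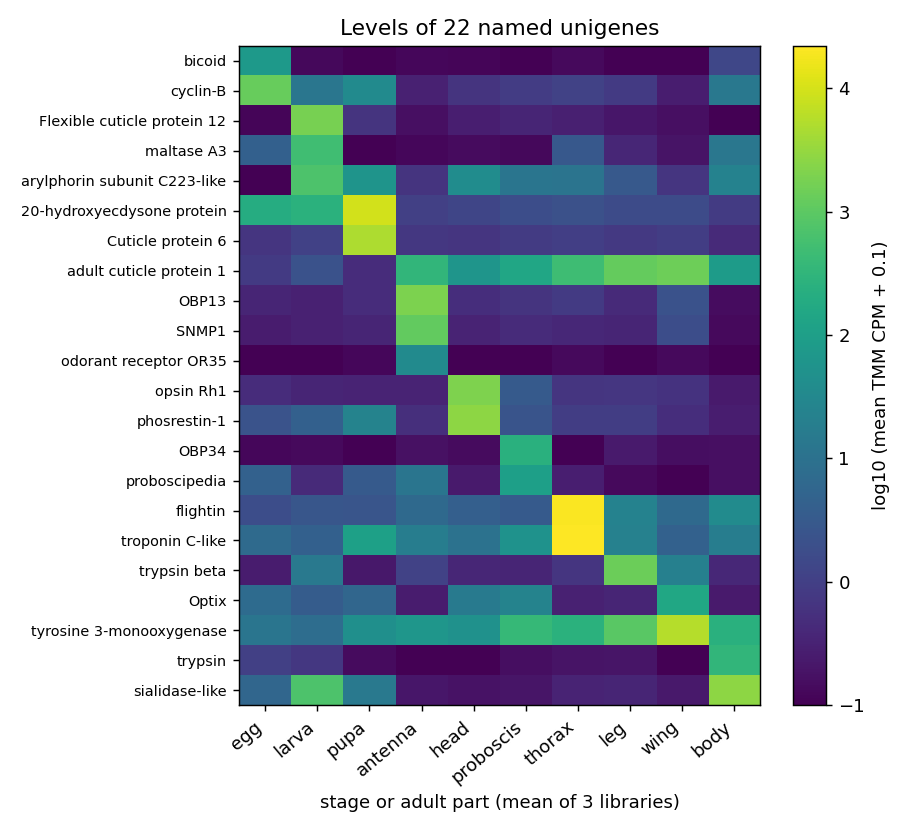
Mean level of 22 named unigenes (vertical axis, annotated name) in the 10 groups (horizontal axis, mean of 3 libraries each), coloured by log10 of the mean TMM CPM plus 0.1. The thorax holds flightin at 19966 CPM and troponin C-like at 21936 CPM, the antenna OBP13 at 1947 CPM, and the head opsin Rh1 at 2007 CPM.

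In 182 of the 195 pairs of a named unigene and a comparison, the libraries of the 2 sides did not overlap. For some of these pairs the rule for naming a unigene required it. The others were also picked for large called changes, so this count repeats the selection and tests nothing. Without such a selection, chance separates 10% of unigenes for 3 against 3 libraries, 0.0988% for 21 against 3 and 0.15% for 3 against 18. Of the 221 named unigenes, 66 had at least 1 other unigene of at least 95% identity over 150 nt, so that their reads can be split between copies.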

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

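The 3 tests on aphid-annotated unigenes and the splits with 2-group models were chosen only after the result was seen. Unigenes whose best hit is an aphid or its endosymbiont stood out because their share of counts lay above that of the highest egg library (0.0482%). It was 3.651% ± 0.627 in larvae (3.28% to 4.38%), 0.4204% ± 0.141 in pupae (0.264% to 0.538%) and 0.05153% ± 0.00271 in heads (0.0484% to 0.0534%), with n = 3 each. The difference between the head and egg libraries was not tested.

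Hoverfly genes whose best database hit is an aphid are argued against. Aphid-annotated ribosomal proteins had a median log2 ratio of larva over adult parts of 8.829 (n = 96, lower quartile 7.481), which is 7.845 above that of other ribosomal proteins (0.9836, n = 82, upper quartile 1.148). Larval RNA carried over into the pupa libraries is argued against, because 58.84% of abundant larva-specific unigenes without an aphid hit (233 of 396) had a pupa over larva ratio under 0.1 of that of the aphid-annotated set (0.06039). RNA of aphids in the larva samples may account for the larval counts and stays open. All 96 of 96 tested aphid-annotated ribosomal proteins were called higher in larvae than in eggs, but so were 3404 of all 3429 aphid-annotated unigenes, so this repeats the pattern and tests nothing. No origin of the pupal counts other than carried-over larval RNA was tested.

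Storage protein unigenes were higher in the head than in the mean of the other adult parts for 28 of 31 members. Their median level was nevertheless higher in the body (8.779 CPM) than in the head (4.785 CPM). The list was higher with the preset correlation (adjusted p = 1.1e-08) but not with the estimated one (adjusted p = 0.147), so the pattern itself is not settled. A share of fat body in the head stays open. Of the rest of the fat body list, 3 of 27 members were called higher in the head and 2 lower, which met the value set against it. The mean that the head was compared with includes the body, where 37 of all 52 fat body members were higher. The test therefore cannot tell a small share of fat body from none. Abdomen material carried into the head libraries stays open. The median head over body ratio of digestive enzymes (0.07748, n = 95) was 0.2327 of that of storage proteins (0.3329, n = 19), between the values set for and against it, and digestive enzymes had an upper quartile of 0.4045. Median levels of the 31 members were 10.6 CPM in pupae, 8.779 in the body, 4.785 in the head, 1.84 in the thorax and 0.1256 in the wing, and a difference between tissues stays open as untested.

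Relative to the mean of the other adult parts, circadian clock unigenes were lower in the head (13 of 20) and higher in the wing (14 of 20). Parts taken at different times of day would move Clock and cryptochrome members against period and timeless, but their median log2 wing over head ratio was 1.595 (3 members, 0.917 to 3.12), in the direction of period and timeless (3.462, n = 16, lowest -0.2022). This argues against a time difference as the whole cause, on 3 members. Several unigenes of 1 gene were counted as separate members, since 16 of the 20 are annotated as period, timeless or timeless homolog. The 14 members that moved carry the names of 3 distinct genes, between the values set for and against this explanation. The list tests treat such unigenes as separate members, so their p values do not rest on 20 genes. How far this shapes the pattern stays open. A difference between tissues stays open as untested.

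Other splits of the same libraries into groups of the same sizes were run for each count. For larva vs egg (17975 called, highest other split 7) and pupa vs larva (12143 called, highest other 2), 1 of 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05. For the 8 other comparisons 1 of 25 splits gave as many, the real one. The real count and the highest other split were 14852 and 2807 for adult parts vs pupa, 12932 and 2416 for the antenna, 11199 and 3832 for the head, 5038 and 4040 for the proboscis, 5687 and 3814 for the thorax, 5385 and 2512 for the leg, 9738 and 4258 for the wing, and 11918 and 3384 for the body. The other splits mix tissues within groups, which raises the spread and favours the real grouping, so they do not tell whether chance can be excluded.

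The 8 comparisons were also fitted with 2 groups, 3 libraries against all others compared. Of 100 such splits as many calls came from 1 for adult parts vs pupa (7569 called, highest other split 2063) and for the antenna (7508, highest other 213), from 2 for the head (5484), the proboscis (261), the thorax (568), the wing (3189) and the body (5624), and from 3 for the leg (136). For these 6 parts the highest other split gave 7508, the count of the 3 antenna libraries, and among the first 25 splits 2 gave as many. The number was raised to 100 after this was seen. In most of the other splits the 3 libraries come from different tissues and the median count was 0, so these splits do not settle it either. The counts of 5038 for the proboscis, 5687 for the thorax and 5385 for the leg come from the model with all groups, and their 2-group counts are far lower.

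For unigenes specific to a group, the highest other split gave 32 for the pupa against the real 651, and 0 for the 9 other groups, and 1 of 25 splits gave as many, the real one. These splits put libraries of different tissues into 1 group, which alone keeps such counts near 0, so they do not tell whether chance can be excluded.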

How the results depend on the processing

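Leaving out aphid-annotated unigenes was chosen only after the data were seen. With RLE or upper quartile scaling, a replicate block or sums over shared annotation, all 20 counts stayed within 1.5 times their value, as did the 10 comparisons with only the libraries compared and all 600 counts with 1 library left out. With no count filter, which tests more unigenes, larva vs egg gave 27344 calls, antenna vs other adult parts 21225, head vs other adult parts 17472 and specific to larva 8737. With the strict filter, which tests fewer, larva vs egg gave 10105, pupa vs larva 6656, adult parts vs pupa 8082, antenna vs other adult parts 6730, head vs other adult parts 6502, proboscis vs other adult parts 3312, leg vs other adult parts 3404, wing vs other adult parts 6242 and body vs other adult parts 6967. For specific unigenes it gave 1722 for specific to larva, 363 for specific to pupa, 817 for specific to antenna, 1338 for specific to head, 151 for specific to leg, 601 for specific to wing and 645 for specific to body. DESeq2 gave 1619 for specific to larva, 412 for specific to pupa and 1490 for specific to antenna, and the cause was not tested. Without aphid-annotated unigenes, specific to larva fell to 1410 because those unigenes were removed.

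A replicate block kept the direction and the call of the 195 named unigene comparisons, the 50 named specific unigenes and the 86 list tests. DESeq2 kept 189 of the 195, ended 5 and gave no adjusted p for 1, and it kept 77 of the 86 counts of called list members within 1.5 times. TRINITY_DN17438_c0_g1 in larva vs egg (40S ribosomal protein S26) turned from -3.10 to 0.142 without egg replicate 3. Its range with 1 library left out was -3.644 to 0.142, and its egg level was 9.84 ± 15.3 CPM. TRINITY_DN4199_c0_g2 in pupa vs larva turned from 10.45 to -1.324 when summed over shared annotation, because other unigenes of that name are added. The list ribosomal proteins in larva vs egg turned direction without aphid-annotated unigenes (adjusted p = 0.857, and adjusted p = 0.976 with an estimated correlation), because 96 of its members were removed. An estimated correlation ended 29 of the 86 list tests and left 57 as they were. Of 1500 checks of the named specific unigenes with 1 library left out, 86 ended a call, all of them in 9 unigenes whose level was within 2.77-fold of the next group. Other shifts of the median log2 fold change above 0.1 were -0.154 (pupa vs larva), 0.188 (adult parts vs pupa), 0.179 (thorax), -0.18 (wing) and -0.105 (body) for RLE scaling, and 0.18 (adult parts vs pupa), -0.114 (head), 0.133 (thorax) and 0.148 (wing) for upper quartile scaling. TMM left medians of 0.364 for larva vs egg and -0.344 for adult parts vs pupa. Unigenes with few counts cannot be told from absent ones below the floors of 0.0614 to 0.137 CPM.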

Other observations

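The Hox test below was set out before its result was seen. Hox genes, which specify segment identity along the insect body, had their most abundant unigene at its highest adult level in the matching body region for 7 of 7 genes found. Proboscipedia (TRINITY_DN10941_c0_g2) was at 102 ± 8.24 CPM in the proboscis (n = 3) and 11.8 ± 1.29 in the antenna. Deformed (TRINITY_DN17433_c0_g1) was at 122.9 ± 4.89 in the proboscis and 0.455 ± 0.391 in the head, and Sex combs reduced (TRINITY_DN13147_c0_g1) at 29.1 ± 3.11 in the proboscis and 8.57 ± 0.154 in the leg. Antennapedia (TRINITY_DN5789_c0_g1) was at 9.22 ± 1.84 in the wing and 8.98 ± 1.02 in the leg, a difference smaller than the SD. Ultrabithorax (TRINITY_DN25373_c0_g1) was at 13.3 ± 2.39 in the leg and 5.82 ± 2.45 in the body. Abdominal-A (TRINITY_DN4031_c0_g1) was at 42.5 ± 3.65 in the body and 0.616 ± 0.556 in the thorax, and Abdominal-B (TRINITY_DN6772_c5_g1) at 3.16 ± 0.507 in the body. The hypothesis that Hox transcripts follow the body region of each part met its prediction in these data.

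Chemosensory unigenes differed in their peak over the 10 groups. Of 38 odorant receptor unigenes over 1 CPM in any group, 35 had their highest mean in the antenna, as had 43 of 45 ionotropic receptors. Of 14 gustatory receptors, 7 peaked in the proboscis and 6 in the antenna. Odorant-binding proteins were spread more widely, with 32 of 115 highest in larvae, 32 in the antenna, 19 in the proboscis, 13 in the body and 12 in the leg. Of 196 cuticle protein unigenes (aphid-annotated included), 85 peaked in larvae, 31 in pupae, 26 in the wing and 21 in eggs. These counts were not tested.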
